A study of Mus musculus with 18 samples.

How the data were processed

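Gene expression was measured in mouse bone marrow derived macrophages, cells grown out of bone marrow with the growth factor CSF1. Per the labels' protocols, marrow came from 3 male C57BL/6 mice aged 10 weeks and was cultured with 10% serum and recombinant human CSF1 at 10000 U/ml for 1 week, then replated. The cells then received 100 nM dexamethasone, a synthetic glucocorticoid, for 1, 2, 4, 10 or 24 h, or were taken at baseline. Each of the 6 groups held 3 arrays, 18 in all, called biological replicates in the series design text. RNA was labelled with biotin and hybridised to Affymetrix arrays, 1 sample per array.

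The deposited table holds 1 intensity per probe set and array on a linear scale, made with RMA in the affy package per the submitters' processing notes, which give no versions. RMA subtracts background, makes the distributions of the arrays alike and summarises the probes of a set, so a change shared by most genes would be removed from these values. The scale was read from the values, which ran from 5.37 to 15224 over the arrays. All 18 columns were mapped to samples by title, and log2 of the intensity was taken before any test. No array depth exists as for reads; the number of arrays limits the precision.

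One stretch of the deposited table holds an even series without the scatter of measurements. In baseline replicate 1, 211 consecutive probe sets had intensities that fell along the row order by a constant log2 step of -0.000106, from 5.352 to 5.330, with no step departing from the mean step by more than 9.12e-10. No run of 10 or more rows with a constant step, within a tolerance of 1e-06, occurred on the other 17 arrays. How these values came about is unknown. All 211 probe sets were left out of every test on all arrays, a choice made after the data had been examined. It removed 174 probe sets with 1 gene symbol, which belonged to 150 genes, and left 77 of those genes with no other named probe set. The same tests with these values kept as they stand, as the analysis was first run, and with them taken as missing on that array alone are in the closing section.

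Of 45141 probe sets, 104 were controls, 28898 had 1 gene symbol, 551 had several and 15588 had none in the annotation used here. By Entrez ID, 28689 were found in the RefSeq gene table and 0 symbols changed. Probe sets with several symbols or none were not named, and some well known genes are unnamed here for that reason. Of the 17097 genes, 7180 had more than 1 probe set; the probe set with the highest mean over the 18 arrays stood for the gene. Genes were kept if at least 3 arrays reached that array's 40th percentile, which left 13190 genes.

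Tests used limma 3.58.1 in R 4.3.3 on log2 intensities, with lmFit over all 18 arrays, 1 mean per group, and eBayes with an intensity trend. Each time was compared with baseline and with the time before it, and an F test covered all 5 times. P-values were two-sided and Benjamini-Hochberg adjusted within each comparison, with a threshold of 0.05; an adjusted p in the text is limma's unless another test is named. P-values measure the spread between replicates. Errors of log2 changes are limma standard errors with n = 3 arrays per group. The design, most alternatives, 29 gene lists with 576 genes and the rule for named genes were fixed before the data were examined; the closing section names the alternatives added later. Of the list genes, 509 were named on the array and 465 tested. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 145 tests of 29 lists at 5 times; a list of 3 genes or more was tested. Calls that hold with an estimated correlation are stated.

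A gene called at 1, 2 or 4 h was sustained if called the same way at 24 h, returned if not called at 24 h and moved back significantly from its largest early value, opposite if called the other way at 24 h, and otherwise undecided; a late gene was called first at 10 or 24 h. Named genes were, at each time, the 6 largest rises and 6 largest falls whose 3 treated arrays all lay on the same side of all 3 baseline arrays, up to 4 passing members of each list or the brightest member where none passed, 5 treatment check genes (Nr3c1, Fkbp5, Tsc22d3, Per1 and Dusp1), the 3 largest rises and falls of each successive step, and the 4 largest members of each timing class and direction. Genes outside that rule are said to be so. A background level of 3.86 log2 was the mean over arrays of the 95th percentile of 43 control probe sets.

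Data were simulated with the real means and spreads of 13190 genes and independent noise, with 50 genes changed by each size. The comparison of 24 h with baseline recovered 100% of genes changed by 2 log2 units and 96% of those changed by 1. It recovered fewer of smaller changes, as given in the closing section. The simulated comparison called 148 genes and the real one 1678, so the recovered shares need not hold for the real comparison. Alternatives covered the replicate number as a block, probe and filter rules, scaling, the variance model, array weights, fold thresholds, the set test and left-out arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No untreated arrays at later times were analysed here, so time in culture and treatment were not separated.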

Results

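The series followed the response of mouse macrophages to dexamethasone over 24 h. It held 18 arrays in 6 groups of 3, at baseline and after 1, 2, 4, 10 and 24 h. Replicates of one group correlated at 0.995 to 0.997 over the tested genes, and between 68.7% and 81.0% of tested genes lay above the background level on an array. The 3' minus 5' difference of the Gapdh control probe sets, a sign of RNA quality, averaged 0.06 log2 at baseline and 0.15 to 0.20 in the treated groups. At 24 h it was 0.20 ± 0.03 (SD, n = 3) against 0.06 ± 0.03, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow, and 0.125 after adjustment over 10 such comparisons. That of Actb averaged 0.38 log2 at baseline and 0.40 to 0.43 in the treated groups. At 24 h it was 0.43 ± 0.03 against 0.38 ± 0.02, with the same exact permutation p of 0.1 and 0.125 after adjustment. The exact permutation p was also 0.1 for Gapdh at 1, 4 and 10 h and for Actb at 2, 4 and 10 h. For Gapdh at 2 h and Actb at 1 h it was 0.3. These tests cannot exclude a difference in RNA quality between baseline and treated arrays, and no comparison with baseline was separated from it. In baseline replicate 1, 211 probe sets carried an evenly stepped series of values, and they were left out of every comparison.

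The first comparison asked which genes differed from baseline after 1 h. Dusp1, a phosphatase that switches off MAP kinases, rose by 3.36 ± 0.09 on the log2 scale. Ddit4, an inhibitor of mTOR signalling, rose by 2.30 ± 0.19, the clock gene Per1 by 2.10 ± 0.10 and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, by 1.80 ± 0.06. Tnf, an inflammatory cytokine, fell by 1.10 ± 0.10 on the log2 scale and Ier3 fell by 0.95 ± 0.10. Fkbp5, a chaperone of the glucocorticoid receptor, was at 0.14 log2 with an adjusted p of 0.999. In total 51 genes changed, 40 upward and 11 downward; adjusting over the 5 times together gave 106. Of 30 tested glucocorticoid receptor targets 7 rose and 1 fell, and 9 rose and 1 fell when adjusted over the list alone. The list shifted upward with a camera adjusted p of 1.15e-18, and with an estimated correlation the adjusted p was 0.00045. With camera on ranks the call was lost at 1 h, with an adjusted p of 0.0928. Rgs2, a member of that list that limits G protein signalling, fell by 0.51 ± 0.08 on the log2 scale. The list of NF-kappaB components and feedback genes, called the NF-kappaB list below, also shifted upward. In it 1 of 19 members rose, Nfkbia at 0.82 ± 0.06, and 4 rose when adjusted over the list alone. Since the list mixes components with feedback genes, its shift at any time does not give a direction of NF-kappaB activity. The list's camera adjusted p was 0.00028, and the adjusted p was 0.356 with an estimated correlation. Nfkbia is also a member of the receptor target list, so these 2 list results are not independent.

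**Figure D1:**
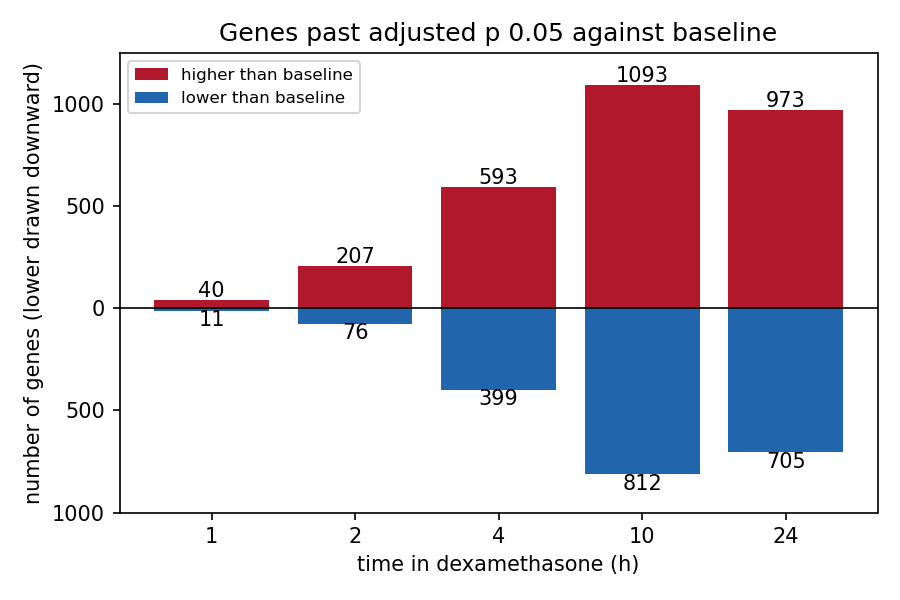
Bars give the number of genes past a limma adjusted p of 0.05 against baseline at each time in hours, with higher genes upward and lower genes downward on a linear axis. The counts run from 40 higher and 11 lower genes at 1 h to 1093 and 812 at 10 h.

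After 2 h the same comparison gave 283 genes, 207 higher and 76 lower than baseline. Fkbp5 had risen by 2.44 ± 0.07 on the log2 scale, Ddit4 by 3.62 ± 0.19 and Il15ra by 2.32 ± 0.18. Klf4, a transcription factor, rose by 1.97 ± 0.09 and Mertk, a receptor for apoptotic cells, by 1.12 ± 0.09. Egr2, an immediate-early transcription factor, fell by 2.36 ± 0.19 on the log2 scale. The chemokines Ccl7 and Ccl2, which attract monocytes, fell by 1.46 ± 0.19 and fell by 1.02 ± 0.10. Among 26 tested inflammatory cytokines and chemokines 5 fell and 0 rose, and 5 fell when adjusted over the list alone. That list shifted downward with a camera adjusted p of 3.01e-06, and the adjusted p was 0.304 with an estimated correlation. Of the 30 receptor targets 11 rose and 2 fell, and 12 and 2 when adjusted over the list alone, with a camera adjusted p of 2.51e-19 and an adjusted p of 0.00045 with an estimated correlation. The interferon-stimulated list shifted upward (camera adjusted p 0.00999), although 0 of its 38 members passed limma's test over all genes, 4 had an unadjusted p under 0.05 and 1 rose when adjusted over the list alone. Its adjusted p was 0.799 with an estimated correlation.

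After 4 h, 992 genes differed from baseline, 593 higher and 399 lower. Fkbp5 stood 3.67 ± 0.07 log2 units above baseline and Lifr, the leukemia inhibitory factor receptor, 3.31 ± 0.17. Zbtb16, a transcriptional repressor, rose by 2.95 ± 0.26, Mertk by 1.88 ± 0.09 and the scavenger receptor gene Cd163 by 1.01 ± 0.15. Acod1, which encodes the enzyme that makes itaconate, fell by 1.80 ± 0.11 on the log2 scale, Plau fell by 1.68 ± 0.13 and Tnf fell by 1.45 ± 0.10. Nr3c1, which encodes the glucocorticoid receptor, fell by 0.27 ± 0.08 on the log2 scale (adjusted p 0.0492). The call for Nr3c1 at 4 h was lost, with an adjusted p of 0.0568, when the evenly stepped values were kept. Over all alternatives its lowest adjusted p was 0.0235. The call was also lost, by construction, where an absolute log2 change of at least 1 was required. Given its error, the fall also lay too near a fold of 1.2 to pass the test against it. The call was thus close to the threshold in the main test. Other probe sets of Nr3c1 were also lower at 4 h, from -0.097 to -0.27 log2. With the probe of largest variance the direction of Nr3c1 reversed at 1 h and 24 h, as given in the closing section. Of 30 receptor targets 15 rose and 1 fell, and 17 and 1 when adjusted over the list alone, with a camera adjusted p of 1.72e-22 and an adjusted p of 0.00045 with an estimated correlation. Of 26 cytokines and chemokines 5 fell, and 6 when adjusted over the list alone, with a camera adjusted p of 0.00314 and an adjusted p of 0.541 with an estimated correlation. The NF-kappaB list had 2 of 19 members rising and 2 falling, and 2 and 6 when adjusted over the list alone, with a median of -0.17 log2 and a camera adjusted p of 0.313. Of 31 cell cycle genes 4 fell, Mcm2 at -0.37 ± 0.07, Cenpe, Mcm4 and Aurka, and 5 when adjusted over the list alone. That list's camera adjusted p was 2.43e-05, and the adjusted p was 0.408 with an estimated correlation. Of 19 cholesterol synthesis genes 1 fell, Hsd17b7 at -0.62 ± 0.18, and 5 when adjusted over the list alone, with a camera adjusted p of 0.000391 and an adjusted p of 0.728 with an estimated correlation.

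**Figure D2:**
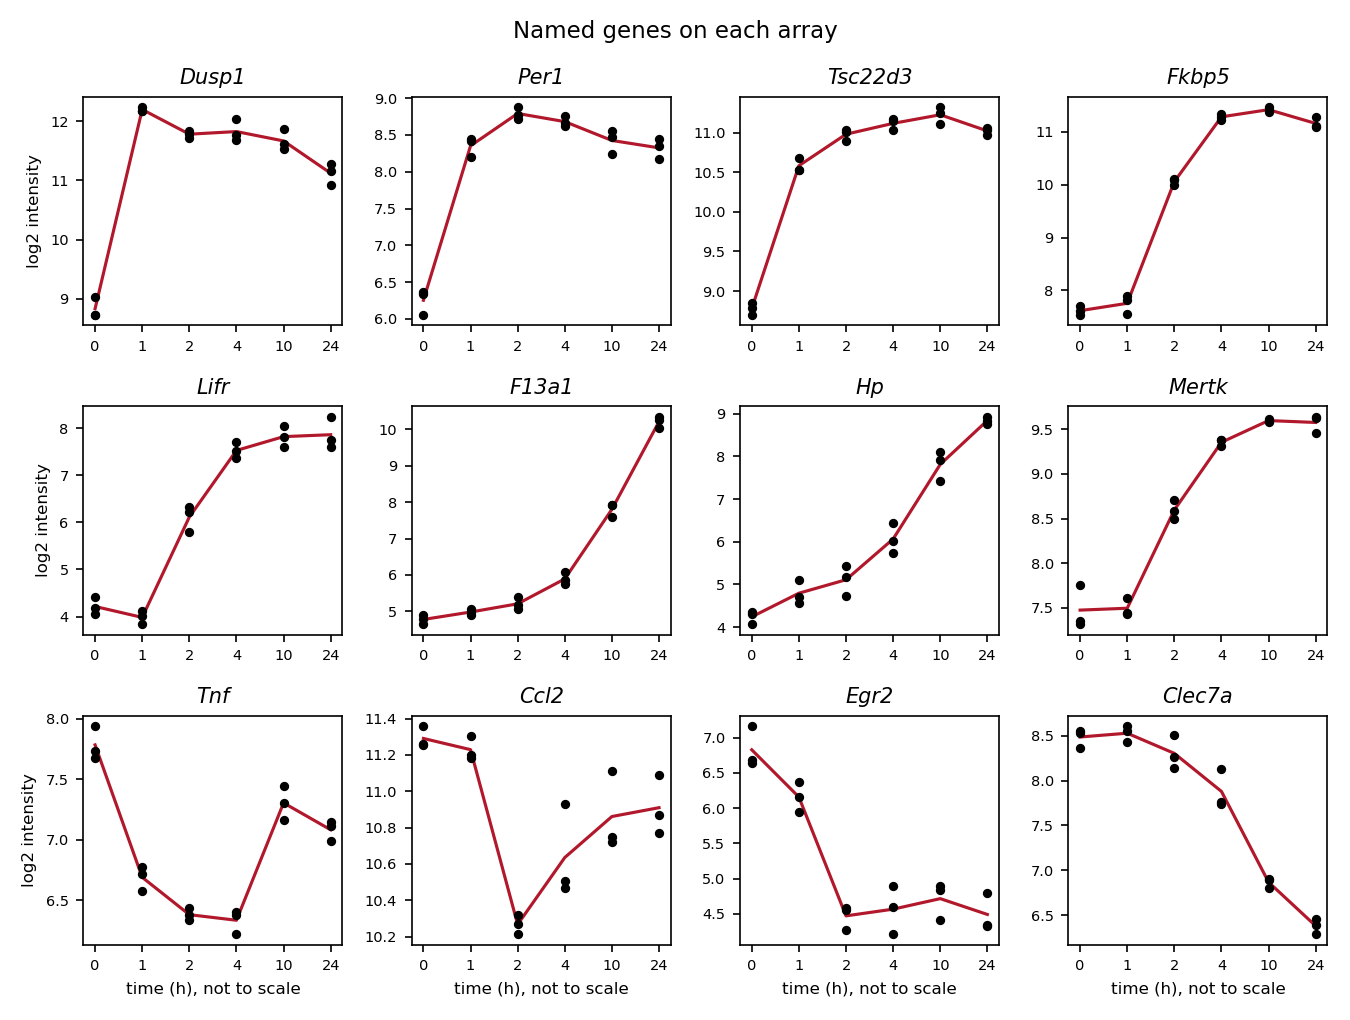
Points give log2 intensity on each array and lines the group means of 3 arrays for 12 genes, against time in hours on an axis that is not to scale. Dusp1 was 3.36 log2 units above baseline at 1 h, while F13a1 reached 5.44 at 24 h.

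After 10 h the number of genes that differed from baseline was 1905, with 1093 higher and 812 lower. Sult1a1, a sulfotransferase, rose by 4.13 ± 0.15 on the log2 scale, Hp, which encodes the haemoglobin-binding protein haptoglobin, by 3.57 ± 0.19 and F13a1, a subunit of coagulation factor XIII, by 3.03 ± 0.13. Cd163, which takes up haptoglobin bound to haemoglobin, rose by 2.09 ± 0.15. Dio2, a thyroid hormone deiodinase, fell by 2.91 ± 0.18 on the log2 scale, and the fungal receptor gene Clec7a fell by 1.62 ± 0.10. Of 30 receptor targets 17 rose and 2 fell, and 17 and 2 when adjusted over the list alone, with a camera adjusted p of 1.18e-15 and an adjusted p of 0.000828 with an estimated correlation. Of 38 interferon-stimulated genes 9 fell and 3 rose, and 10 and 3 when adjusted over the list alone. Ifit1 fell by 1.35 ± 0.21, Rsad2 fell by 1.34 ± 0.19 and Ifit2 fell by 1.15 ± 0.22 on the log2 scale; the list's camera adjusted p was 0.017 and the adjusted p was 0.815 with an estimated correlation. Complement and coagulation genes shifted upward, with 8 of 15 rising and 1 falling, and 8 and 1 when adjusted over the list alone. The camera adjusted p was 0.00504 and the adjusted p was 0.209 with an estimated correlation. Of 21 genes of Toll-like receptor signalling, which include more than the receptors, 5 rose and 1 fell, and 6 and 1 when adjusted over the list alone. Tlr8 stood at 1.95 ± 0.16 and Tlr7 at 1.32 ± 0.07. That list's camera adjusted p was 0.0122 and the adjusted p was 0.151 with an estimated correlation. The NF-kappaB list had 6 of 19 members higher, and 6 when adjusted over the list alone, with a camera adjusted p of 0.00578 and an adjusted p of 0.505 with an estimated correlation. Among 19 cholesterol synthesis genes 3 fell, and 8 when adjusted over the list alone, with a camera adjusted p of 0.000104 and an adjusted p of 0.717 with an estimated correlation. The 26 cytokines and chemokines did not shift at 10 h, with 3 rising and 3 falling, and 3 and 6 when adjusted over the list alone (camera adjusted p 0.207). Fitting only the baseline and 10 h arrays gave 1257 genes at this time.

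After 24 h, 1678 genes differed from baseline, 973 higher and 705 lower. F13a1 stood 5.44 ± 0.13 log2 units above baseline, Hp 4.60 ± 0.19 and Saa3, an acute phase protein gene, 3.28 ± 0.11. Ms4a4b rose to 7.35 ± 0.14 log2 (SD, n = 3) from a baseline mean below the background level, which leaves the size of its rise uncertain. Cdkn1c, an inhibitor of the cell cycle and a member of the receptor target list, fell by 2.51 ± 0.21 on the log2 scale, and Mmp12, the macrophage elastase, fell by 2.38 ± 0.12. Il1rn, which encodes the interleukin 1 receptor antagonist, fell by 2.08 ± 0.17. Of 30 receptor targets 17 rose and 3 fell, and 18 and 4 when adjusted over the list alone, with a camera adjusted p of 1.58e-09 and an adjusted p of 0.00661 with an estimated correlation; with camera on ranks the call was lost, with an adjusted p of 0.0565. Of 15 complement and coagulation genes 8 rose and 2 fell, and 8 and 2 when adjusted over the list alone, with C1qa at 0.96 ± 0.08. The camera adjusted p was 0.000104 and the adjusted p was 0.0866 with an estimated correlation. Of 17 genes of MHC class II and costimulation 4 fell, and 6 when adjusted over the list alone, with H2-Aa at -1.35 ± 0.17. The camera adjusted p was 0.0209 and the adjusted p was 0.14 with an estimated correlation. Glycolysis and hypoxia genes shifted downward, with 5 of 17 falling and 1 rising, and 6 and 1 when adjusted over the list alone; the camera adjusted p was 0.0104 and the adjusted p was 0.138 with an estimated correlation. Of 14 oxidative stress and metal response genes 6 fell, Srxn1 at -0.85 ± 0.08 among them, and 3 rose, and 7 and 3 when adjusted over the list alone, with a camera adjusted p of 0.012 and an adjusted p of 0.275 with an estimated correlation. Of 21 genes of Toll-like receptor signalling 6 rose and 2 fell, and 7 and 3 when adjusted over the list alone. That list's camera adjusted p was 0.0122, and the adjusted p was 0.151 with an estimated correlation. For the NF-kappaB list, with 7 of 19 rising and 7 when adjusted over the list alone, the camera adjusted p was 0.0412 and the adjusted p was 0.653 with an estimated correlation. In the model used here the calls of the receptor target list held with an estimated correlation at all 5 times, and those of the other lists did not. Further calls held with the replicate number as a block, an alternative added after the data were seen. These were cytokines at 2 h (camera adjusted p 0.019), cholesterol synthesis at 10 h (0.0444) and complement and coagulation at 24 h (0.0428).

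Some lists that did not shift held genes that moved both ways at 24 h. Among 21 genes for uptake of apoptotic cells 7 rose and 7 fell, and 7 and 8 when adjusted over the list alone. Mertk rose by 2.10 ± 0.09 and the scavenger receptor gene Stab1 by 1.05 ± 0.10, whereas Itgb3, an integrin subunit, fell by 1.52 ± 0.21 on the log2 scale. Among 21 alternative activation markers 7 rose and 4 fell, and 7 and 4 when adjusted over the list alone, with Cd163 at 2.55 ± 0.15 and Clec7a at -2.11 ± 0.10. Among 20 lipid handling genes 3 rose and 6 fell, and 3 and 6 when adjusted over the list alone, with Apoc2 at 2.24 ± 0.11 and Pparg at -0.98 ± 0.09. Among 26 cytokines and chemokines 3 rose and 4 fell, and 3 and 4 when adjusted over the list alone, with a camera adjusted p of 0.292. Of 11 neutrophil markers 2 rose and 3 fell, and 2 and 3 when adjusted over the list alone, with Mmp8 at 1.59 ± 0.16 and S100a9 at -1.18 ± 0.20.

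Successive times were compared to find when genes moved. From 1 h to 2 h 148 genes changed, 116 upward and 32 downward, with Fkbp5 up by 2.30 ± 0.07, Lifr up by 2.13 ± 0.17 and Egr2 at -1.69 ± 0.19. From 2 h to 4 h 251 genes changed, 153 upward and 98 downward, with Zbtb16 up by 2.17 ± 0.26 and Acod1 at -1.39 ± 0.11. From 4 h to 10 h 551 genes changed, 310 upward and 241 downward, with F13a1 up by 1.91 ± 0.13 and Il1rn at -1.41 ± 0.17. From 10 h to 24 h 285 genes changed, 131 upward and 154 downward, with F13a1 up by a further 2.41 ± 0.13 and Saa3 by 1.86 ± 0.11. The clock gene Cry1 changed by -1.77 ± 0.08 and Mmp12 by -1.72 ± 0.12 in that step. With the replicate number as a block the counts of the last 3 steps, and those against baseline at 1 h and 2 h, were higher, as given in the closing section. Single arrays left out in turn lowered counts by more than 1.5 times. The count from 2 h to 4 h was 137 without 4 h replicate 2, 143 without 4 h replicate 1, 144 without 2 h replicate 2, 160 without 2 h replicate 1 and 167 without 4 h replicate 3. From 4 h to 10 h the count was 316 without 4 h replicate 1 and 334 without 4 h replicate 2, without 24 h replicate 1 that from 10 h to 24 h was 145, and without 1 h replicate 3 that from 1 h to 2 h was 90. The last 3 steps gave 129, 321 and 124 genes without an intensity trend and 142, 359 and 172 with the probe of largest variance; the mean of all probes gave 157 from 2 h to 4 h, and fitting only the groups compared gave 344 and 176 in the last 2 steps.

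**Figure D3:**
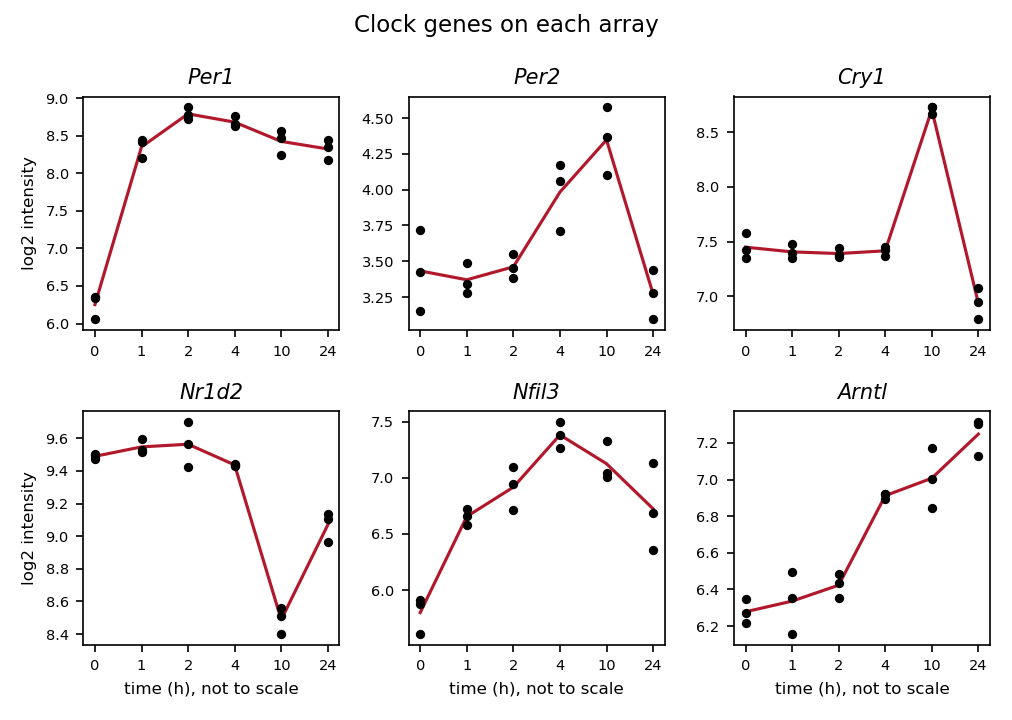
Points give log2 intensity on each array and lines the group means of 3 arrays for 6 clock genes, against time in hours on an axis that is not to scale. Cry1 was 1.26 log2 units above baseline at 10 h and at -0.51 relative to it at 24 h; Per2 lay near the background level.

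Over the whole series the F test called 2300 genes, and 2709 genes were called at 1 or more times. Of genes called at 1, 2 or 4 h, 401 that rose and 201 that fell were sustained at 24 h, among them F13a1, Ddit4, Egr2 and Plau. Another 84 that rose and 107 that fell had returned, among them B3gnt5, Fgl2, Ccl7 and the iron exporter gene Slc40a1; without 4 h replicate 2 the returned genes numbered 122 in place of 191. The remaining early genes were undecided, 116 that rose and 100 that fell, or opposite at 24 h, 5 that rose first and 6 that fell first. Late genes numbered 879 rising and 810 falling, with Saa3, Cbr2, Mmp12 and Cdkn1c among the largest. Of the 40 genes higher at 1 h, 34 were higher at 24 h, where independent lists would share 2.95, and of the 11 lower genes 9 were lower at 24 h, against 0.59. In 50 simulations of 6 unchanged groups that shared 1 baseline, the 40 and 973 genes ranked highest for a rise shared 23.2 genes on average, with a range of 15 to 33. The 11 and 705 genes ranked highest for a fall shared 6.58 on average, with a range of 3 to 10. Few genes passed the threshold in these simulations, 0.02 at 1 h and 0.14 at 24 h on average, and the called genes shared 0. The 34 shared higher genes lay just above the simulated range for top ranks, and the 9 shared lower genes lay within theirs. The simulated genes were all unchanged, so these ranges do not measure how much of the real overlap came from the shared controls. Both comparisons used the same 3 baseline arrays, too few to split, and part of the excess over independent lists may come from the shared controls.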

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

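Of the tests in this part, the comparison with other probe sets of the same genes and the counts of other splits were chosen before their results were seen; the tests of the treated replicate 1 cultures, the filled series, the clock genes and the neutrophil markers were chosen after.

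Genes were called in opposite directions at 2 times, with the direct difference between those times past the threshold, in 17 cases. The log2 difference, later minus earlier time, was -1.77 for Cry1, -1.44 for Fgf13, -0.94 for Tef, -0.69 for Ephx1 and -0.61 for Mthfd1l between 10 h and 24 h. It was -0.59 for Kitl between 4 h and 10 h, -0.49 for Slc20a1 between 2 h and 24 h, and between 4 h and 24 h -0.53 for Frmd4a, -0.53 for Glipr1 and -0.46 for Syne1. Genes that were lower first and higher later were Adipor1 at 0.38, Lcp2 at 0.72, Cnrip1 at 0.95, Nfkbiz at 1.15 and Ccl12 at 1.16 between 4 h and 24 h, Pnrc1 at 0.46 between 2 h and 10 h, and Tlr2 at 0.88 between 4 h and 10 h. Fgf13, Tef, Cry2 (in a later paragraph), Ephx1, Mthfd1l, Syne1, Adipor1, Pnrc1 and Lcp2 lie outside the rule for named genes and were chosen after their values were seen. When the evenly stepped values were kept, Nfkbiz at 4 h and Ccl12 at 24 h were no longer called. Their adjusted p-values were then 0.0618 and 0.0675. Over all alternatives the lowest adjusted p was 0.00188 for Nfkbiz at 4 h and 0.000647 for Ccl12 at 24 h. Both calls were also lost, by construction, where an absolute log2 change of at least 1 was required. At -0.51 log2 for Nfkbiz at 4 h and 0.54 for Ccl12 at 24 h, both changes also lay too near a fold of 1.2, given their errors, to pass the test against it. Nfkbiz at 4 h was close to the threshold in the main test, with an adjusted p of 0.0441. Among probe sets with no gene symbol, which the comparisons of genes do not use, 780 of 9485 changed at any time against baseline by the F test.

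Baseline replicate 1 had 56 genes at least 1 log2 unit below both other baseline arrays, with a median difference of -2.68. The explanation written down before its test, a fault in single probe sets of that array, met its prediction, since 14 other probe sets of the same genes had a median difference of 0.12. It was set aside only after the values were seen in table order, because all 56 genes lay on one unbroken run of 211 probe sets with a constant log2 step, which scattered faults would not give. A lower level in the replicate 1 cultures is argued against by a median difference of 0.011 in the 5 treated replicate 1 arrays. A series filled in along the row order is what stays open, with 56 of the 56 genes in the run. When and how this may have happened was not tested. No biological explanation other than a lower level in the cultures was tested.

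Clock genes differed between 10 h and 24 h: 5 of 19 tested were called, Cry1, Per2, Tef, Cry2 and Nr1d2. The mean absolute change of the list was 0.39 log2, above the highest of 10000 random lists of the same size and expression, which was 0.29. An aberrant 10 h array is argued against, since with each of the 3 arrays at 10 h left out in turn the lowest mean was 0.38, where the highest random list was 0.33. The hour of the day at harvest cannot be told apart from treatment: 3 of the 5 genes still differed from baseline at 24 h, but the labels give no hour and no untreated arrays at later times were analysed here. A response of the clock to dexamethasone may also account for the difference and stays untested.

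Neutrophil markers moved apart at 24 h: Mmp8 at 1.59 and Lcn2 at 1.80 log2 rose, while Ngp at -1.13, Ltf at -0.90 and S100a9 at -1.18 fell. Errors in this paragraph are standard errors of an ordinary linear model of the difference between 2 genes, not of limma. Fewer granulocytes in the 24 h cultures were predicted to lower all their markers alike, which leaves the rises of Mmp8 and Lcn2 without an account. Among 4 markers at least 3 log2 units above background, the highest change, of Mmp8, and the lowest, of S100a9, lay 2.77 ± 0.28 apart. These genes were picked as the extremes of the same 24 h changes, so their difference restates the pattern and is not a separate test of it. As the cause of the 3 falls, fewer granulocytes cannot be told apart from a change within the cells. The falls were alike, with a largest difference of 0.29 ± 0.24. However, S100a8, at -0.093, did not pass the test and differed from S100a9 (S100a9 minus S100a8 -1.09 ± 0.15). Levels at the background of the arrays are argued against, since the lowest of the higher group means over the 5 called members was 5.20 log2, against a background of 3.86. A change of the risen genes within the macrophages may account for Mmp8 and Lcn2 and stays untested.

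For each comparison of 3 against 3 arrays, 10 splits are too few for a share under 0.05. The real split gave 51, 283, 992, 1905 and 1678 genes at 1, 2, 4, 10 and 24 h, and 148, 251, 551 and 285 in the successive steps; in each of these 9 comparisons 1 of 10 splits gave a count as large, and the highest other split gave 0. For gene lists adjusted within each time, the real split gave 2, 3, 4, 8 and 7 lists and the highest other split 6, 6, 7, 6 and 7. The number of splits with a count as large was 5 at 1 h, 4 at 2 h, 4 at 4 h, 1 at 10 h and 2 at 24 h. At 1 h another split thus gave 6 lists against the real 2. At the preset correlation the number of lists did not set the real split apart at 1, 2, 4 and 24 h. Each other split keeps part of the difference between the groups, and the cause was not tested. For the F test 1 of 100 random splits, the real one, gave 2300 genes, and the highest other gave 474. That share lay under 0.05, which argues against a random grouping of the arrays there. It is the smallest share that 100 splits can give, and the splits ignored the replicate numbers.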

How the results depend on the processing

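The evenly stepped values, their removal and the removal of the 3 arrays of lowest weight were chosen as alternatives after the data had been seen, as was the replicate block with estimated correlation; the others were planned. With the evenly stepped values kept, the counts were 49, 276, 964, 1848 and 1629 genes at the 5 times, 141, 229, 510 and 251 in the 4 steps and 2214 by the F test; 111 tested genes then rested on the run, 18 of them called, and 15 calls of named genes were lost. With those values taken as missing on that array the counts at the 5 times were 51, 289, 999, 1918 and 1687. Signal near background limits genes such as Per2 and Cd55, and 3 arrays per group limit small changes. In the simulation with 50 genes changed by each size, 68% of those changed by 0.5 log2 units at 24 h were recovered. Of those changed by 0.25, 20% were recovered.

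The labels do not say what a replicate number marks. Of 45 same-numbered pairs 35 had a correlation of deviations over 0.1, with a range of 0.02 to 0.29. Their median was 0.15, against -0.079 for differently numbered pairs. Each of the 18 arrays correlated best with its own number, a hint from the data and not from the design. With the replicate block the counts were 93 at 1 h, 432 at 2 h, 500 from 2 h to 4 h, 945 from 4 h to 10 h and 547 from 10 h to 24 h. A threshold of 1 on the absolute log2 change left, by construction, 10, 48, 98, 126 and 136 genes at the 5 times, 17, 9, 25 and 19 in the steps, and 58 sustained, 33 returned and 100 late genes. Testing against a fold of 1.2 left 23, 107, 243, 386 and 370, then 36, 20, 60 and 26, and 149 sustained, 24 returned and 317 late genes. Without a trend 129, 321 and 124 genes changed in the last 3 steps, and with the probe of largest variance 142, 359 and 172, with 11 lists at 10 h. The mean of all probes gave 157 genes from 2 h to 4 h. With only the groups compared 1257 genes changed at 10 h, 344 from 4 h to 10 h and 176 from 10 h to 24 h. Adjusting over the 5 times together gave 106 genes at 1 h, and testing 24 h against the mean of 1, 2 and 4 h gave 83 returned genes. The number of shifted lists was 1 at each of the 5 times with an estimated correlation, and camera on ranks gave 0 at 1 h and 0 at 24 h. With fry it was 6, 8, 12 and 13 from 2 h on. Unlike camera, fry tests a list against no change and not against the other genes, so its counts answer another question. The replicate block with estimated correlation gave 1 list at 1 h, 2 at 2 h, 1 at 4 h, 2 at 10 h and 2 at 24 h: the receptor targets at each time, cytokines at 2 h (camera adjusted p 0.019), cholesterol synthesis at 10 h (0.0444) and complement and coagulation at 24 h (0.0428). Without the 3 arrays of lowest weight 4 lists shifted at 1 h and 6 at 2 h. Apart from settings that raise the fold or drop arrays, the cause was not tested.

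With each array, and each replicate number, left out in turn the counts ranged from 34 to 55 at 1 h, 195 to 298 at 2 h, 580 to 1076 at 4 h, 1002 to 1902 at 10 h and 925 to 1810 at 24 h. The steps ranged from 77 to 164, 88 to 283, 224 to 585 and 74 to 314, the F test from 1304 to 2273, and sustained, returned and late genes from 345 to 657, 83 to 207 and 889 to 1804. Shifted lists, 2, 3, 4, 6 and 7 of 29 at the 5 times, ranged from 2 to 5 at 1 h, 2 to 7 at 2 h, 3 to 5 at 4 h, 5 to 9 at 10 h and 6 to 9 at 24 h. Returned genes numbered 122 without 4 h replicate 2, and from 4 h to 10 h 334 genes changed without that array; from 2 h to 4 h 167 changed without 4 h replicate 3. Lists at 1 h numbered 4 without baseline replicate 1, baseline replicate 2 or 1 h replicate 2, and 5 without 1 h replicate 3; at 2 h 7 shifted without baseline replicate 2. Reversed directions were Nfatc1 at 24 h, -0.045 with the mean of all probes; with the probe of largest variance Nfatc1 at 10 h, -0.32, and at 24 h, -0.21, Itgav at 4 h, 0.15, and Nr3c1 at 1 h, 0.090, and at 24 h, 0.26; and Nr3c1 at 10 h, 0.030 without replicate 2, with a range of -0.18 to 0.030 over the left-out numbers. The cause was not tested. Over all alternatives, 13607 of 14960 values of named genes and counts of rising or falling genes kept their direction and side of the threshold or stayed within 1.5 times; 1219 kept the direction alone, 127 counts moved further and 7 reversed. Other scalings moved the median change by less than 0.02 log2.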

Other observations

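Of 19 clock genes 6 rose and 3 fell at 10 h, and 6 and 3 when adjusted over the list alone, with a camera adjusted p of 0.0508. Arntl, a core activator of the clock, rose by 0.73 ± 0.11 on the log2 scale at 10 h and by 0.97 ± 0.11 at 24 h, and the repressor gene Nfil3 by 1.33 ± 0.15 and 0.92 ± 0.15. Nr1d2 fell by 1.00 ± 0.06 on the log2 scale at 10 h. Of 5 mast cell and basophil markers 1 fell at 24 h, and 1 when adjusted over the list alone; it was Kit, a receptor of mast cells and progenitors, at -1.32 ± 0.16. Of 19 genes of endoplasmic reticulum and amino acid stress 2 rose and 3 fell at 24 h, and 5 and 6 when adjusted over the list alone, with Herpud1 at 0.59 ± 0.09 and Chac1 at -0.94 ± 0.24.

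At 24 h 2 of 12 heat shock genes fell, and 2 when adjusted over the list alone, among them Ahsa1 at -0.60 ± 0.07. Of 6 Fc receptor genes 3 rose and 2 fell, and 4 and 2 when adjusted over the list alone, with Fcgrt at 0.96 ± 0.11. Of 25 immediate-early genes 4 rose and 5 fell, and 5 and 5 when adjusted over the list alone. Of 22 signalling brakes 2 rose and 7 fell, and 3 and 7 when adjusted over the list alone, with Dusp4 at -1.10 ± 0.10. Of 12 genes of the receptor and its cofactors 2 rose and 1 fell, and 2 and 2 when adjusted over the list alone. Of 18 macrophage identity genes 5 rose and 4 fell, and 7 and 5 when adjusted over the list alone, with Itgam at 0.55 ± 0.08 and Ccr2 at -0.77 ± 0.20. Of 8 osteoclast markers 1 rose and 2 fell, and 2 and 3 when adjusted over the list alone, and of 5 dendritic cell markers 1 fell, and 2 when adjusted over the list alone. In limma's test 0 of 9 lymphocyte, 0 of 7 erythroid and megakaryocyte and 0 of 3 stromal markers changed, and 0 of each when adjusted over the list alone; 1, 0 and 0 had an unadjusted p under 0.05. The median, the mean and the camera direction differed in sign at 24 h for the immediate-early, heat shock, clock and receptor and cofactor lists, none of which was called then.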
